A study of Populus davidiana with 6 samples.

How the data were processed

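Leaf RNA was measured in 6 libraries of Populus davidiana, an Asian aspen, all from the cultivar Odae19, which the labels class as drought tolerant. Per the labels' protocols, the plants were grown in vitro and were about 6 weeks old. For the treatment they were taken out of the medium, rinsed and kept in open air for about 10 min. Unless the controls were also removed and rinsed, the effects of removal, rinsing and drying cannot be told apart here. The words air-dried and air-drying stand for the whole treatment. There were 3 control and 3 air-dried libraries, and each library's group was taken from its title. Per the labels' protocols, poly(A) RNA was fragmented and made into TruSeq RNA libraries, which were read as paired ends of 100 bp on an Illumina HiSeq sequencer. This kit does not mark the strand, so reads from overlapping genes on opposite strands cannot be told apart. Nothing in the labels says that the replicates came from separate plants or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

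The deposited values are FPKM (fragments per kilobase of transcript, scaled to the fragments of the library), per the file headers, with 1 value per transcript and library and no scaling between libraries stated. The submitters' processing notes name FastQC, TopHat and Cufflinks, without versions or roles. The genome build, the annotation version and any filter are not given in the sources used here. Coordinates are printed as the files give them, counted from 1. The files list 112919 transcripts, of which 45773 are marked as annotated and 67146 as assembled from reads, grouped into 40537 gene identifiers. In 1307 transcripts no strand is given. The column for gene names is empty in every line (0 names), and no genome or name table was used here, so the files do not pair identifiers with names. For that reason at most 2 identifiers that rose and 2 that fell are printed, and their functions are not given.

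FPKM carries no read counts, so the sequencing depth of each library is not known in absolute terms. Relative depth was estimated from annotated single-transcript genes spanning over 1500 bp whose values in both libraries were near the worth of 1 fragment. Only genes with an absolute log2 ratio to control 1 under 0.35 were kept, so larger differences in depth could not show. Against control 1, the estimates were 1.03 for control 2 (73 genes), 1.08 for control 3 (62 genes), 0.985 for air-dried 1 (47 genes), 0.966 for air-dried 2 (67 genes) and 1.13 for air-dried 3 (67 genes). Any value printed as listed at 0 can be a failed estimate as well as an absence of reads, and no fold change is given for it in the text.

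The design written before the data were examined foresaw FPKM per gene. Because the files hold transcripts, the FPKM of all transcripts of a gene was summed, a choice made after the files were seen. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 22559 genes and set 17978 aside. The test was limma 3.58.1 (lmFit and eBayes with an intensity trend, 2-sided) in R 4.3.3 on log2(FPKM + 1), with the group as the sole term. Its p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called higher or lower. A 2-fold change means a log2 difference of at least 1 on the log2(FPKM + 1) scale, which understates the change of genes with low values. The same limma test was run on the 41109 transcripts that passed the same filter.

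Genes were named by a rule fixed before the data were examined. It took the 5 largest rises and the 5 largest falls among called genes whose 3 libraries of one group all lay above the 3 of the other, and the first 2 of each are printed. The other parts of that rule, and the tests of 26 gene lists fixed in advance (drought, hormone, photosynthesis, ribosome, defence and cell type genes), needed gene names or descriptions. They were not run (0 lists filled). Alternatives for count data were not run because the values are FPKM, and those on a quantification status were not run because the status column holds the annotation status.

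Calls on chromosomes were compared by Fisher's exact test, and pairs of neighbouring called genes were compared with 10000 permutations of the calls within each chromosome. Gene span is the genomic distance from the first to the last base of a gene's transcripts, introns included. Spans and transcript numbers of called genes were compared by Fisher's exact test and with 10000 random gene sets matched on mean expression. These comparisons of position, span and transcript number were chosen after the files were seen.

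The limma tests were first run on simulated data with 200 changed genes or transcripts and variances taken from the real libraries. The neighbour test and the removal of each library's trend with span were also tried on simulated data. The Fisher's exact tests and the matched random sets were not. The simulated noise was independent between genes and held no structure among libraries beyond the 2 groups, so the false calls below do not cover such a structure. At the gene level, 76% of changes of log2 1 and 93% of changes of log2 2 were recovered among 22559 genes, with 8 false calls. At the transcript level, 1% and 25% were recovered among 41109 transcripts, with 1 false call, so transcript counts miss most changes of those sizes. Tests of transcript usage within genes were also tried on simulated data. One made too many false calls and another recovered none of the planted changes, so neither was used.

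The alternatives tried were other pseudocounts (0.1 and 5 FPKM), other filters, rescaling, median centring, quantile normalization, other variance models, library weights, the replicate number as a block, and each library left out in turn. After the data were seen, further alternatives were added. These used annotated transcripts alone, transcripts spanning at least 200 bp, a term for a second split of the libraries, the removal of each library's trend with span, and 4 libraries without control 3 and air-dried 1. Tables were read with data.table (version 1.17.8) and plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.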

Results

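Gene expression was measured by poly(A) RNA sequencing in leaves of the drought-tolerant aspen cultivar Odae19, in 3 libraries from control plants and 3 from plants air-dried for about 10 min. The series title and design text present the comparison as a transcriptome profile of drought stress brought on by the drying. Between 22075 and 22404 genes per library reached 1 FPKM, and the median FPKM of the tested genes lay between 11.3 in control 3 and 11.9 in air-dried 3.

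The summed FPKM differed far more between libraries than the medians did. It was 2031732, 3958425 and 3257030 FPKM in controls 1, 2 and 3 and 1835112, 4180878 and 1711808 FPKM in air-dried 1, 2 and 3. The 526 transcripts with a genomic span of up to 150 bp held most of this difference, with 45.6%, 73.3% and 73.1% of the sum in the controls and 38.6%, 77.2% and 40.1% in the air-dried libraries. The largest transcript alone took 60.3% of the sum in air-dried 2 and 5.38% in control 1.

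Across the tested genes, log2 values correlated at r = 0.933 to 0.959 between libraries of one group and at 0.911 to 0.943 between libraries of different groups. These correlations are across genes, which are not independent replicates. The first principal component held 34.5% of the variance and the second 27.0%. Controls 1 and 2 scored −48.5 and −51.9 on the first component and air-dried 2 and 3 scored 48.4 and 36.7. Control 3 (3.35) and air-dried 1 (11.98) lay between them, and these 2 libraries were farthest apart on the second component (−51.3 and 64.5).

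In the fit of all 6 libraries, most called genes were higher in the air-dried leaves (83.8%, against 59.1% without control 3 and air-dried 1). Of 22559 tested genes, 814 were higher and 157 were lower in the air-dried leaves, 971 in all (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05, n = 3 libraries per group). In the 6 libraries the rises were also larger, with a median log2 fold change of 1.04 among the higher genes and −0.67 among the lower genes. A change of at least 2-fold was seen in 425 higher and 25 lower genes, at least 4-fold in 152 and 9, and at least 16-fold in 24 and 1. On the log2(FPKM + 1) scale a fall is bounded by the control level and a rise is not, so these sizes are not directly comparable. At a mean of at least 10 FPKM, 46.9% of higher and 8.82% of lower genes changed 2-fold in 6 libraries. Without control 3 and air-dried 1 the shares were 49.1% and 57.8%, so the larger rises were not seen there. The median log2 fold change of all tested genes was 0.0037.

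On the log2(FPKM + 1) scale the largest rises were those of POPTR_0009s16050 and POPTR_0018s08320. POPTR_0009s16050 is an annotated single-transcript gene on the plus strand of chromosome 9 (12284978 to 12286144). Its level was 3.28 ± 0.167 FPKM in the controls and 291 ± 14.3 FPKM in the air-dried leaves (SD, n = 3). The log2 fold change was 6.09 (SE 0.072, limma with Benjamini-Hochberg adjusted p = 3.4e-06). POPTR_0018s08320 is also an annotated single-transcript gene, on the plus strand of chromosome 18 (9245946 to 9246542). It was at 0.498 ± 0.482 FPKM in the controls and 96.7 ± 34.3 FPKM after drying (SD, n = 3), a log2 fold change of 6.02 (SE 0.31, limma adjusted p = 0.00025). The order of these genes depended on the setting, and with a pseudocount of 0.1 FPKM the log2 fold change was 6.43 for POPTR_0009s16050 and 7.58 for POPTR_0018s08320. What these genes encode is not given, because the files do not pair identifiers with names.

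On this scale the called gene with the largest fall was XLOC_008625, a locus on chromosome 11 (2866714 to 2866849) known from assembled reads alone, with no strand given. It measured 46.4, 51.1 and 29.4 FPKM in controls 1, 2 and 3 and was listed at 0 in each of the 3 air-dried libraries (limma adjusted p = 8.9e-05). Its span of 136 bp placed it in the class of very short transcripts that held 38.6% to 77.2% of the summed FPKM. The second was POPTR_0014s00750, an annotated gene on the minus strand of chromosome 14 (705608 to 706214). It measured 8.95, 15.6 and 2.75 FPKM in the controls and was listed at 0 in all 3 air-dried libraries (limma adjusted p = 0.029). The call of POPTR_0014s00750 was lost under 7 of 21 alternative settings, with an adjusted p of up to 0.121 without air-dried 3. None of the 4 printed genes overlapped another gene of the files (0 overlaps each), whereas 13.1% of all higher and 15.3% of all lower genes did.

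**Figure D1:**
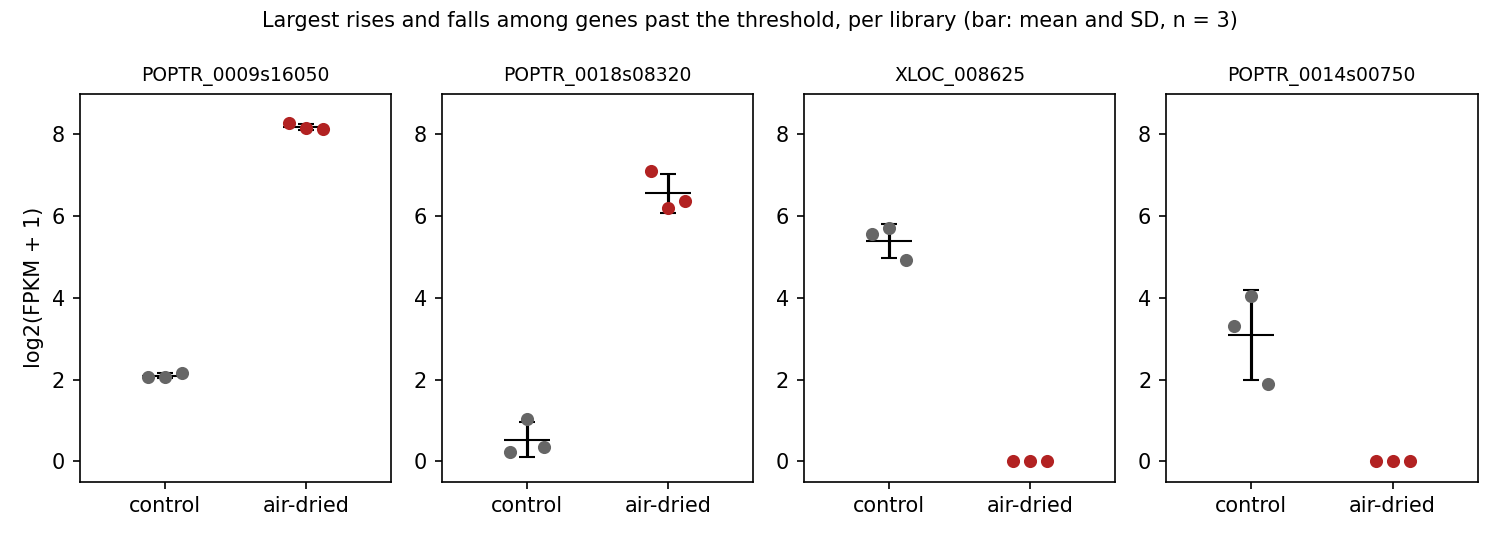
Level of the 4 named genes in each library, as log2(FPKM + 1) on the vertical axis, for control (grey) and air-dried (red) leaves. Points are single libraries, and bars are the mean and SD of 3 libraries, left out where all 3 are listed at 0. POPTR_0009s16050 and POPTR_0018s08320 were higher in all 3 air-dried libraries, and XLOC_008625 and POPTR_0014s00750 were listed at 0 in all of them.

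Many of the higher genes were scarcely detected in the controls. In 176 of the 814 higher genes all 3 controls were under 1 FPKM, and in 17 of these all 3 air-dried libraries reached at least 10 FPKM. The converse was rarer, with 12 of the 157 lower genes under 1 FPKM in all air-dried libraries and 6 of them listed at 0 in all 3. A gene under 1 FPKM in all libraries of one group passed the filter only if all 3 of the other group reached 1 FPKM. The direction of such genes was thus set by the filter, and they also enter the shares by level given next. How many tested genes had either pattern was not counted. The median control level was 3.91 FPKM for the higher genes, 10.2 FPKM for the lower genes and 11.5 FPKM for all tested genes. The share of tested genes called higher was 6.58% where the mean over the 6 libraries was under 2 FPKM, 4.31% from 2 to 5 FPKM, 3.12% from 5 to 20 FPKM, 3.32% from 20 to 100 FPKM and 1.75% at 100 FPKM or more. For lower genes the shares in these classes were 0.513%, 1.12%, 0.729%, 0.477% and 0.606%. Among the 12477 genes with a mean over the 6 libraries of at least 10 FPKM, 367 were higher and 68 were lower in the fit of all 6 libraries, whereas 442 were higher and 393 lower without control 3 and air-dried 1. Of the 12311 genes with a control mean of at least 10 FPKM, 241 were higher and 81 lower in the fit of all 6 libraries.

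**Figure D2:**
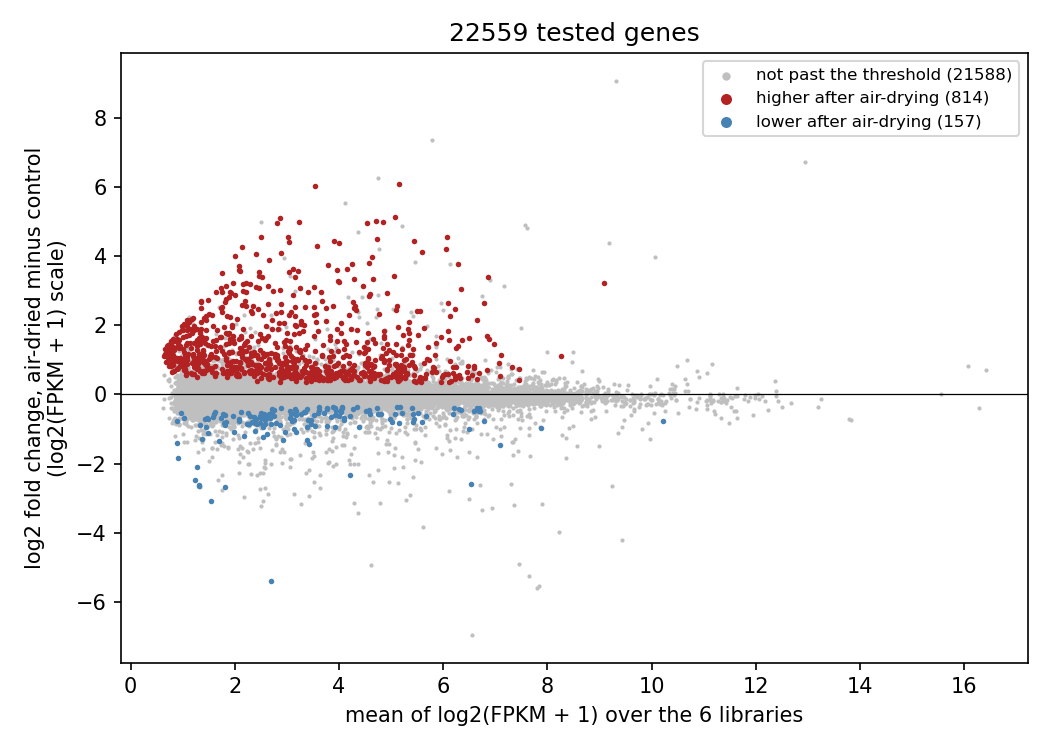
Log2 fold change (air-dried minus control, log2(FPKM + 1) scale) against the mean of log2(FPKM + 1) over the 6 libraries for 22559 tested genes. Each point is a gene; red marks the 814 higher and blue the 157 lower genes. Some genes with differences as large as those of the coloured points were not past the threshold (grey).

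The counts moved with the choice of libraries. Leaving out 1 library at a time gave 578 called genes without control 1, 536 without control 2, 568 without air-dried 2 and 477 without air-dried 3. Over all 6 such fits there were 435 to 581 higher and 42 to 120 lower genes. With control 3 and air-dried 1 both left out, 784 genes were higher and 543 lower, so that 59.1% of called genes were higher in place of 83.8%. In these 4 libraries 482 higher and 323 lower genes changed at least 2-fold. There the labelled contrast is also that of the second division given below, which called 238 of the 543 lower and 78 of the 784 higher genes in the same direction.

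A second division of the libraries, which no label names, also set many genes apart. When all 10 ways of dividing the 6 libraries into 3 and 3 were tested with limma, the labelled division gave 971 genes. The division that sets controls 1 and 2 and air-dried 1 against control 3 and air-dried 2 and 3 gave 511. No other division gave more than 6. Of the 511 genes, 392 were lower in control 3 and air-dried 2 and 3. These had a median span of 1332 bp and a median level of 49.9 FPKM, against 3521 bp and 11.8 FPKM for all tested genes. The sign of a trend with span followed the same division. The rank correlation across genes between span and a library's deviation from the gene mean was −0.21, −0.042 and −0.26 in controls 1 and 2 and air-dried 1. It was 0.29, 0.19 and 0.0053 in control 3 and air-dried 2 and 3. With a term for this second division in the model, 982 genes were higher and 254 lower after air-drying, and 887 of the 971 genes were called again.

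**Figure D3:**
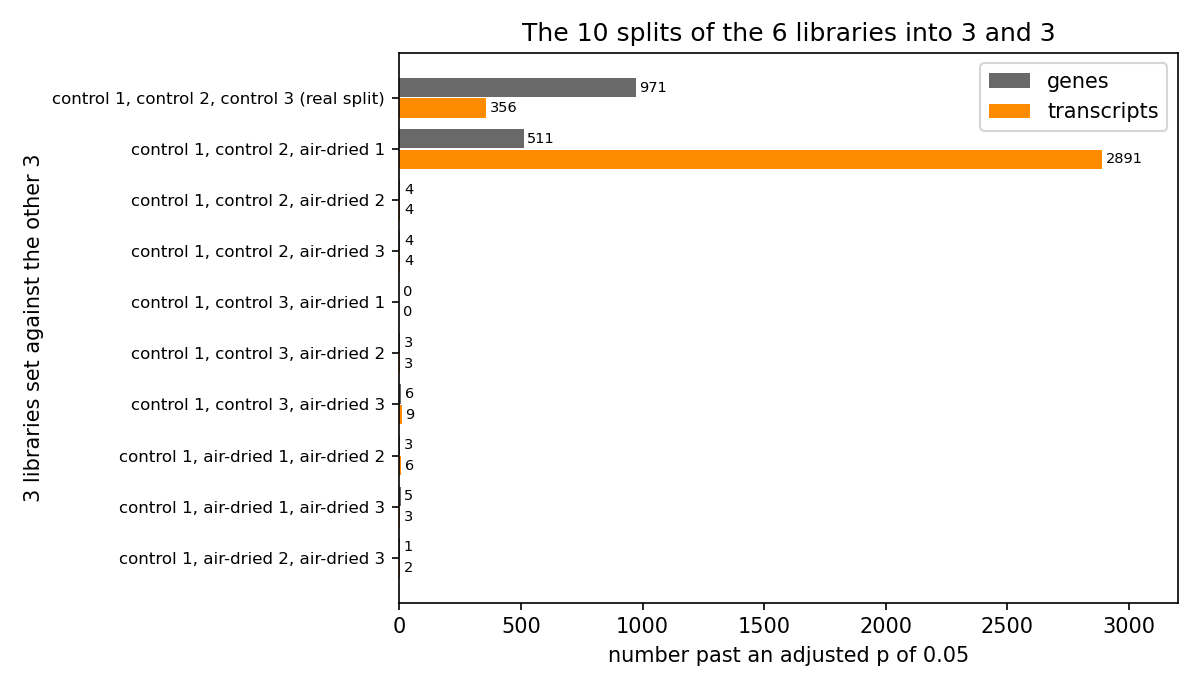
Number of genes (grey) and transcripts (orange) with an adjusted p under 0.05 for each of the 10 divisions of the 6 libraries into 3 and 3, labelled by the libraries set against the other 3. The labelled division gave 971 genes and 356 transcripts, and the division with controls 1 and 2 and air-dried 1 on one side gave 511 genes and 2891 transcripts.

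The higher genes were shorter and had fewer transcripts than the genes tested. Their median genomic span was 1965 bp, against 2624 bp for the lower genes and 3521 bp for all tested genes. Short span was also seen in the second division, where the 392 genes lower in control 3 and air-dried 2 and 3 had a median of 1332 bp. Whether that division is free of the treatment is not known. A single transcript was listed for 458 of the 814 higher genes (56.3%), for 63 of the 157 lower genes (40.1%) and for 26.1% of tested genes. The odds ratio of a single transcript was 3.85 for higher genes (95% interval 3.34 to 4.46, Fisher's exact p = 1.17e-76) and 1.90 for lower genes (1.36 to 2.65, Fisher's exact p = 0.000119). Counting annotated transcripts alone, it was 1.44 for higher genes (1.18 to 1.76, Fisher's exact p = 0.000178). The share called higher was 1.21% among genes spanning under 500 bp, 8.34% from 500 to 1000 bp, 9.03% from 1000 to 2000 bp, 3.36% from 2000 to 4000 bp, 1.27% from 4000 to 8000 bp and 2.42% at 8000 bp or more. Within single-transcript genes the higher genes had a median span of 1423.5 bp, close to the 1386 bp of the tested ones, and within genes of several transcripts it was 3210.5 bp against 4311.5 bp.

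**Figure D4:**
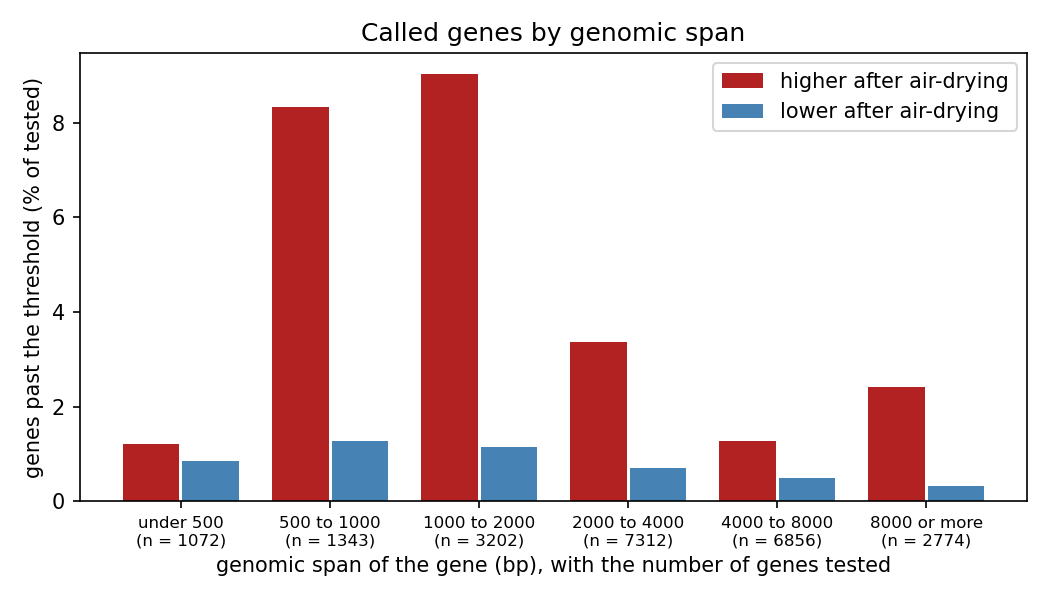
Share of tested genes called higher (red) or lower (blue) after air-drying, in percent, by genomic span of the gene in bp, with the number of genes tested in each class. The share of higher genes was largest from 1000 to 2000 bp (9.03%) and from 500 to 1000 bp (8.34%).

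Loci known from assembled reads alone were seldom among the higher genes. Of 1320 such tested loci, 19 were higher (1.44%, against 3.74% of loci with an annotated transcript, Fisher's exact p = 1.93e-06). The lower genes included 17 of them (1.29% against 0.659%, Fisher's exact p = 0.0150), 6 of these with no strand given. Assembled transcripts spanning over 150 bp held 41.9 ± 3.25% of the FPKM of all transcripts of that span in the controls and 44.3 ± 0.814% in the air-dried leaves (SD, n = 3). This difference did not pass an exact permutation test (2-sided p = 0.2, where 3 against 3 cannot go below 0.1).

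At the level of single transcripts, 356 of 41109 were called, 320 higher and 36 lower (limma with Benjamini-Hochberg adjustment). Annotated transcripts made up 261 of the higher and 17 of the lower ones. The called transcripts belonged to 345 genes, of which 308 were also called as genes and 37 were not. In 3 genes, transcripts were called in both directions.

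The called genes were spread over the genome. The share of tested genes called higher ranged from 2.78% to 4.51% over the 19 chromosomes and the pooled unplaced scaffolds, and the share called lower from 0.125% to 1.24%. None of the 40 Fisher's exact tests passed after Benjamini-Hochberg adjustment (0 in each direction), while 0 tests for higher and 2 for lower genes had an unadjusted p under 0.05. The lowest unadjusted p was 0.159 for higher and 0.0314 for lower genes. Among 21072 neighbouring pairs of genes that did not overlap, 35 had both members higher, where permuted calls gave 27.3 on average (permutation p = 0.0794, adjusted p = 0.0933). For lower genes there were 3 such pairs, where permuted calls gave 1.08 (permutation p = 0.0933, adjusted p = 0.0933).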

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

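Of the alternatives here, those on annotated transcripts, transcripts of at least 200 bp, the second division, the span trend and 4 libraries were chosen after the data were seen. Over 22 alternatives the count of 971 called genes ranged from 416 to 2516. Among settings that can turn a direction, annotated transcripts alone did so, with 826 of 843 genes keeping theirs. Rescaling, centring, quantile normalization and the span trend turned none of the 971, and transcripts of at least 200 bp none of 969. The other settings, the term for the second division among them, could not turn a direction, because the groups of all 971 genes were separate. Rescaling the libraries to one common sum gave 416 genes (356 higher, 60 lower; 292 of them among the 971) and moved the median log2 fold change of all genes to 0.27. A mean of at least 5 FPKM gave 553 (468 higher, 85 lower, 253 at 2-fold), with fewer genes tested. Annotated transcripts alone gave 538 (486 higher, 52 lower), and library weights gave 2516 (1730 higher, 786 lower). These weights, estimated from the same data, were lowest for air-dried 1 (0.407) and control 3 (0.559). They were highest for air-dried 3 (3.27) and control 2 (2.27). The weighted fit thus leaned toward the 4 libraries in which the labelled and the second division coincide. The lower genes alone moved to 254 with a term for the second division and to 249 with the span trend removed. Without control 3 and air-dried 1 together there were 543 lower genes and 805 at 2-fold, and a pseudocount of 5 gave 228 at 2-fold. The causes of these shifts were not tested. The sum used for rescaling includes the very short transcripts, which held 38.6% to 77.2% of it.

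With the replicate number as a block, 557 genes were called (497 higher, 60 lower). Deviations from the group means of samples with the same number correlated at 0.24, −0.15 and 0.12, and not every sample correlated best with its own number. Between the groups, these correlations were positive for samples on the same side of the second division and negative for samples on opposite sides. They followed that division and cannot decide whether the shared numbers mark pairs.

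Leaving out 1 library gave 477 to 693 genes, 435 to 581 higher and 42 to 120 lower. The total moved by over 1.5 times without control 1 (578), control 2 (536), air-dried 2 (568) and air-dried 3 (477). POPTR_0009s16050, POPTR_0018s08320 and XLOC_008625 stayed past the threshold in every alternative in which they were tested. POPTR_0014s00750 was lost with a pseudocount of 5, with the replicate block, and without control 1, control 2, air-dried 1, air-dried 2 or air-dried 3. Its limma adjusted p was 5.37e-08 with rescaling alone. Over its other alternatives it ran from 0.00255 without control 3 to 0.121 without air-dried 3. The tests of gene lists and those for counts or quantification status were not run. The odds ratio of a single listed transcript, annotated or assembled, in higher genes (3.85) was 12.5 with rescaling, 6.43 for calls made on the FPKM of annotated transcripts, 2.39 with no filter and 2.34 with library weights. The median span of higher over tested genes (0.558) was 0.334 with rescaling. Absolute depth is not known, so it cannot be said at which level a listed 0 excludes expression.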

Other observations

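Of the tests in this part, rescaling, median centring and quantile normalization were set before the data were examined. The others, and what each test was taken to weigh, were chosen after the results were seen. Each explanation is a hypothesis tested on the data it was found in.

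The labelled division of the 6 libraries gave the largest count of genes, 971 against 511 for the highest of the others, and the largest count at 2-fold, 450 against 248. For each of these, 1 of 10 divisions reached the real count, and 10 divisions cannot give a share under 0.05. For transcripts, 2 of 10 divisions did, because the division that sets control 3 and air-dried 2 and 3 apart gave 2891 transcripts against 356, which points to a structure of the samples that the labels do not name.

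Depth and a trend with gene length were weighed as sources of this second division. Depth stays open, since control 3 and air-dried 3 were the deepest libraries (relative depth 1.08 and 1.13) while air-dried 2 on the same side was the shallowest of the 6, with 0.966 (95% bootstrap interval 0.951 to 0.986) against 1 in control 1, 1.03 in control 2 and 0.985 (0.981 to 0.989) in air-dried 1, a difference of −0.0192 from the last, and a single library decides nothing here. A trend with span as the whole source is at odds with the 389 genes called after each library's trend was removed, 335 of them among the 511. The median absolute log2 difference over the 511 genes was 0.89 in place of 0.97. The sign of the trend followed this division, though the trend was near nil in air-dried 3 (rank correlation 0.0053) and weak in control 2 (−0.042). It may account for part of the division. An exchange of the labels of control 3 and air-dried 1 would turn one division into the other. Of the genes called from the other 4 libraries that placed these 2 on opposite sides, 61.5% placed both with their own label (683 against 427, 95% interval 58.6 to 64.4%), where a swap alone would give few and correct labels with no other factor nearly all, so it cannot be told apart from an unlabelled batch or condition (2891 transcripts), and no day, batch or plant is labelled that could decide it.

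The excess of rises over falls (83.8% of called genes) may be partly a matter of which libraries were compared. Scaling as the whole source is at odds with the lowest share over 3 scalings, 79.4% with quantile normalization. Rescaling and median centring weigh little here. Rescaling moved the median log2 fold change of all genes to 0.27, toward rises. Median centring moved it only from 0.0037 to −0.011. Falls hidden near the floor were weighed as the whole source of the share in 6 libraries. Where the mean over the 6 libraries was at least 10 FPKM, 84.4% of called genes were higher (95% interval 80.6 to 87.7%). Genes near the floor in the controls could enter this class only through their rise, so it cannot decide alone. Where the control mean was at least 10 FPKM, a bound that favours falls, 241 genes were higher and 81 lower. This is at odds with hidden falls as the whole source in 6 libraries. Without control 3 and air-dried 1 the share was 59.1% (95% interval 56.4 to 61.7%) over all levels. It was 52.9% at a mean over the 6 libraries of at least 10 FPKM. In these 4 libraries, however, the labelled and the second division coincide. Of their 543 lower genes 238 were also lower in the second division, and of their 784 higher genes 78 were also higher. The same 4 libraries enter both fits, so what control 3 and air-dried 1 add stays open. A candidate explanation, that synthesis can act within minutes while falls wait for decay, asks for more 2-fold changes among rises. At a mean over the 6 libraries of at least 10 FPKM the odds ratio was 9.08 (3.81 to 26.3, Fisher's exact p = 3.93e-10) in 6 libraries but 0.706 (0.531 to 0.936) in 4. That class also holds genes that entered it through their rise, so the explanation stays open too.

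The short span of the higher genes, with a median of 1965 bp, was set against their expression level, a trend with span, precision and assembly. Random sets matched on mean expression had a median of 3309.5 bp (95% range 3113.5 to 3520.5; permutation p = 1e-04, the smallest that 10000 sets can give), and with each library's trend removed the median of the higher genes was 1965 bp (1875 to 2094). Single-transcript genes were not measured more precisely, with a residual SD 1.46 times that of other genes at the same level, and the annotated span alone, which does not depend on assembly, was 1921 bp in higher genes and 3334 bp in tested genes. The excess of genes with 1 transcript is less clear, since for the same calls the odds ratio was 3.85 when all listed transcripts of a gene were counted and 1.44 (1.18 to 1.76, Fisher's exact p = 0.000178) when its annotated transcripts were, so part of it may come from fewer transcripts being assembled for genes scarcely detected in the controls. Short span did not go with rises throughout, since within single-transcript genes the higher genes spanned 1423.5 bp against 1386 bp in the tested ones, and 1.21% of genes under 500 bp were higher. The 392 genes lower in control 3 and air-dried 2 and 3 were also short, with a median span of 1332 bp. An exchange of labels between control 3 and air-dried 1 stays open. These genes therefore cannot show whether short span is particular to air-drying.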
